A study of Mus musculus with 3 samples.

How the data were processed

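RNA of Hepa1c1c7 cells, a mouse hepatoma line, was measured on 3 Agilent mouse gene expression arrays of 1 colour (Cy3). The cells had been transfected with an empty vector, a Cd74 vector or a Tmem54 vector, per the labels, and each vector has 1 array. All 3 arrays lay on the same slide, so slide does not separate the vectors. Groups were taken from the transfection label of each sample.

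The deposited intensity of each spot was made with Agilent Feature Extraction 12.0.3.1, per the submitters' processing notes and the file headers. The authors' files hold a processed signal, which is a linear intensity after spatial and multiplicative detrending, per the file headers. Its error model takes a multiplicative error of 0.1, per the file headers. A deposited value table of the series was also compared with the arrays. Its values equal the processed signal divided by 1 constant per array, 580.3 for the empty vector, 559.8 for Cd74 and 580.7 for Tmem54, which lie close to the 75th percentiles over all spots of 580.3, 559.8 and 580.6. Its scale is thus linear and uncentred, and its column medians were 0.0409, 0.0393 and 0.039.

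Each array has 62976 spots, of which 59305 are not controls and carry 56605 probes. On each array 300 probes are printed 10 times. Spots well above background made up 57.2% of the spots other than controls for the empty vector, 56.1% for Cd74 and 55.7% for Tmem54. No such spot was saturated on any array (0 spots). Between 119 and 135 spots per array carried an outlier flag and were left out, with the control spots.

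The value used was the log2 processed signal minus the 75th percentile of its array over all spots other than controls. Replicate spots of a probe were averaged on the log2 scale. A gene took the value of its probe with the highest mean over the 3 arrays, among probes well above background on at least 1 array. Where a probe was not well above background on 1 of the arrays compared, the difference is a bound. The bright array was then set against the higher of the dim array's lowest signal well above background and the probe's own, and the result is written as at least N-fold. The size of such a bound holds for the main setting only. A gene was counted at a difference of at least 2-fold.

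Gene symbols came from a reference table of assembly GRCm38.p6, matched for 33762 probes by accession, for 9871 by symbol and for 310 by a unique synonym. The remaining 12662 probes have no symbol there and entered no comparison of genes. Of 24842 genes on the array, 15796 were well above background on at least 1 array, and 6972 of these had more than 1 such probe. Probe coordinates are those of the array files on build mm9, and none were converted.

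With 1 array per vector there is no spread between cultures, so no test was run and no p-value is given. The number of arrays limits the precision of every value. The SD between replicate spots had a median of 0.036 on the log2 scale for the empty vector, 0.038 for Cd74 and 0.036 for Tmem54. The error of the processed signal had a median of 0.145 on the log2 scale on each array. It is a model value that for bright spots follows mainly from the preset multiplicative error of 0.1, and not a spread measured between spots. Both refer to noise within an array only.

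A total of 45 gene lists were fixed before the data were examined. The median difference of each list was set against 10000 random lists of the same size, matched on deciles of mean expression, and a list was said to stand apart below percentile 2.5 or above percentile 97.5. At least 5 members well above background on 1 of the arrays compared were needed. These percentiles describe these arrays only.

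The genes named follow a rule fixed before the data were examined. It takes the transfected genes, the genes the series description names, and the 10 highest and 10 lowest differences from the empty vector among genes well above background on all 3 arrays whose brighter signal reached the median of detected probes. It adds the 3 largest bounds per direction, the 5 highest and 5 lowest genes of Cd74 against Tmem54 under the same limits on signal, and up to 4 members of each list with the largest differences. Of the 10 highest genes for Cd74 against empty, 1 is not reported here.

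The counting and list steps were tested on simulated data for Cd74 against empty with 15239 genes, of which 30 formed a planted list. All 50 genes planted at each of 2.5-fold, 4-fold and 8-fold were counted, 0 of 50 planted at 1.5-fold were counted, and 0 of 15009 unchanged genes were counted. Of 200 unchanged lists, 9 stood apart. A list planted at 0.4 on the log2 scale gave a median of 0.38. The simulated noise was equally large for dim and bright genes, far below 2-fold, and independent between genes. These counts therefore check that the steps run as described and give no error rate for the real arrays or for lists of related genes.

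Alternatives were normexp background correction with an offset of 50, median centring over detected probes, quantile normalization, the authors' value table, the 75th percentile over probes well above background on all arrays, stricter and no filters on dim probes, other ways to go from probes to genes, and thresholds of 1.5-fold and 3-fold. Values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and normexp in limma 3.58.1 under R 4.3.3.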

Results

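Gene expression in Hepa1c1c7 mouse hepatoma cells was compared after transfection with an empty vector, a vector for Cd74 (the invariant chain of MHC class II, also a receptor for the cytokine MIF) or a vector for Tmem54 (a transmembrane protein). Each vector was measured on 1 array, so no value has a replicate and no difference was tested. The number of spots well above background was 33896 for the empty vector, 33250 for Cd74 and 33049 for Tmem54. The error from the processed signal was between 0.20 and 0.21 on the log2 scale for most differences of the bright genes named, and it covers noise within the arrays only.

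Both transfected genes were far brighter on their own array. The Cd74 probe (chromosome 18, 60972075 to 60972132, build mm9) had a processed signal of 26.8 with the empty vector, 10860 with the Cd74 vector and 22.4 with the Tmem54 vector, a log2 difference of 8.73 from the empty vector. The Tmem54 probe (chromosome 4, 128788699 to 128788758) had a signal of 19750 with the Tmem54 vector and was not well above background on the other arrays. In the main setting this gave a difference of at least 1494-fold from the empty vector and at least 1387-fold from the Cd74 vector. Across the alternative settings the log2 difference from the empty vector ranged from 8.23 to 10.59, so the size of the bound depends on the setting.

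The series description names 3 genes in connection with Cd74, and because they were chosen on these samples their directions are not independent evidence. Trib3, a pseudokinase induced by stress (chromosome 2, 152163161 to 152163220), had a signal of 3624 with the empty vector and 10580 with Cd74, a log2 difference of 1.61 ± 0.20 (model error of the processed signal). Id3, an inhibitor of basic helix-loop-helix factors (chromosome 4, probe span 135700075 to 135700249), went from 4813 to 1969, a difference of -1.22 ± 0.20. Atoh8, a basic helix-loop-helix transcription factor (chromosome 6, 72156816 to 72156875), went from 415 to 133.9, a difference of -1.57 ± 0.21. With the Tmem54 vector the differences from the empty vector were -0.35 for Trib3, 0.20 for Id3 and 0.50 for Atoh8. Each of the 3 genes was read by 1 probe.

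**Figure D1:**
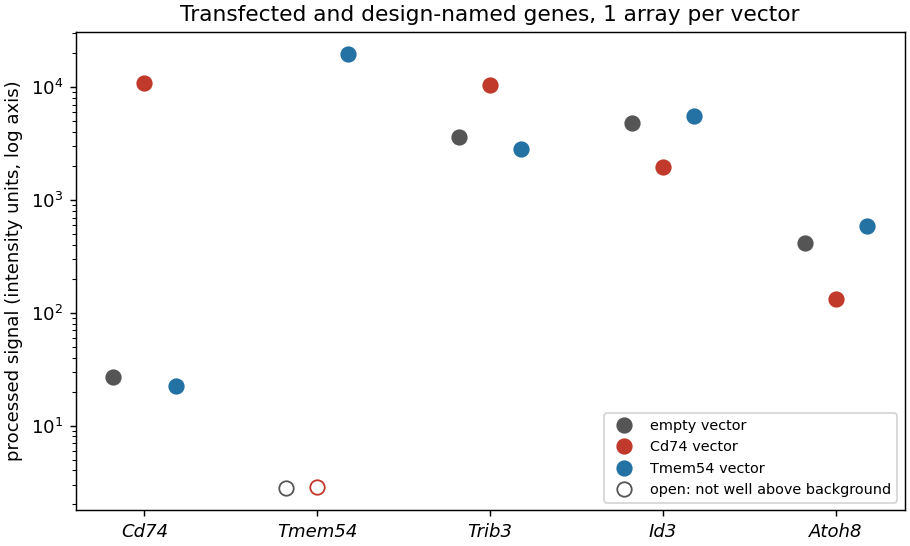
Processed signal (intensity units, log axis) of Cd74, Tmem54, Trib3, Id3 and Atoh8 on the empty-vector, Cd74 and Tmem54 arrays, 1 point per array, open where not well above background. Trib3 reads 10580 on the Cd74 array against 3624 on the empty-vector array, and Atoh8 reads 133.9 against 415.

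Compared with the empty vector, the Cd74 array was higher for genes of the ATF4 and amino acid response and of the NRF2 oxidative stress response, and lower for BMP and ID genes, interferon-stimulated genes, mitotic genes and sterol synthesis genes. Of 15630 genes compared, 160 were at least 2-fold higher and 219 at least 2-fold lower. Of these, 98 of the higher and 89 of the lower genes were bounds. Centring on the median of detected probes instead gave 126 higher and 290 lower, so that 30.3% of the genes counted were higher against 42.2% in the main setting. Normexp correction left 58 higher and 61 lower, and a filter for bright genes left 25 and 33.

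The ATF4 list had a median of 0.47 over 30 members, 1 of them a bound (percentile 100), with 5 at least 2-fold higher and 0 lower. They were Trib3, the cystine transporter gene Slc7a11 (1.57), the glycine transporter gene Slc6a9 (1.5), the phosphatase subunit gene Ppp1r15a (1.20) and Chac1 (1.16), which encodes a glutathione-degrading enzyme. Without Trib3 the median was 0.46. The next-brightest probes of 12 members gave 0.22. The NRF2 list had a median of 0.26 over 28 members (percentile 100), with 4 at least 2-fold higher and 0 lower. Heme oxygenase Hmox1 differed by 1.93, and the other 3 were the glutathione transferase gene Gsta2 and, held by both lists, Slc7a11 and Trib3. Without members of the ATF4 list the NRF2 median was 0.24. The immediate early list had a median of 0.30 over 31 members (percentile 100), led by Nr4a2 (1.01) and Atf3 (0.95). The lysosome list had a median of 0.26 over 23 members (percentile 100), led by the autophagy receptor gene Sqstm1 (1.22).

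Lower on the Cd74 array were ID and BMP genes, with a median of -0.32 over 12 members (percentile 0.02) and 3 at least 2-fold lower. These were Atoh8, Id2 (-1.41) and Id3, and Id1 differed by -0.94. Without Id3 and Atoh8, which the series description names, the median was -0.21 (percentile 1). A filter for bright genes, which keeps only part of the list and does not leave out Id3 and Atoh8, gave -1.08. Interferon-stimulated genes had a median of -0.44 over 37 members (percentile 0.00), with 7 at least 2-fold lower and 0 higher. Irf7, a transcription factor of the interferon response, differed by -1.43, Oas2 by -1.33 and the ubiquitin-like modifier gene Isg15 by -1.30. Normexp correction gave -0.27, and next-brightest probes of 15 members gave -0.16. All 32 mitotic genes of the G2/M list were below 0, with a median of -0.49 (percentile 0.00) and 0 at least 2-fold lower. The centromeric histone gene Cenpa differed by -0.73 and the kinesin gene Kif11 by -0.69. The sterol synthesis list had a median of -0.61 over 23 members (percentile 0.00), with 22 members below 0 and 0 at least 2-fold lower. Next-brightest probes of 17 sterol synthesis members gave -0.40, with 15 below 0. Nsdhl differed by -0.91, the lanosterol synthase gene Lss by -0.74 and Fdft1, for squalene synthase, by -0.70. Beside these groups, the hepatocyte marker list had a median of -0.20 over 25 members (percentile 0.11), with Alb at -0.87, and the fibroblast and stellate cell markers had -0.16 over 12 members (percentile 1.09). Normexp correction gave -0.030 for the hepatocyte markers.

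Measured single genes are ranked here among bright genes only, meaning those well above background on all 3 arrays whose brighter signal reached the median of detected probes. On the Cd74 array the highest bright genes after Cd74 itself were Cox6a2, a subunit of cytochrome c oxidase (2.38), Angptl6, an angiopoietin-like secreted protein (1.98), Hmox1, and Acot2, a mitochondrial acyl-CoA thioesterase (1.67). Guf1 differed by 1.51, while its next-brightest probe gave -0.06. The lowest bright genes were Angpt1, a ligand of the Tie2 receptor (-2.06), Tcstv3 (-2.00), Gm4340 (-1.97), AF067061 (-1.91), BB287469 (-1.85), AA684185 (-1.83), H2-Q1, an MHC class I gene (-1.77), Gm20767 (-1.76), Atoh8 and Mndal, of an interferon-inducible family (-1.56). Several of these belong to families of near-identical copies, so their probes may read more than 1 gene. The largest bounds were at least 22.2-fold higher for Pdcd1, which encodes the PD-1 receptor, 17.7-fold for the kynureninase gene Kynu and 17.19-fold for 4930539C22Rik. On the lower side they were at least 12.11-fold for Lipo1, 11.51-fold for Dact1 and 10.03-fold for Pik3c2g, whose next-brightest probe gave -0.44.

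**Figure D2:**
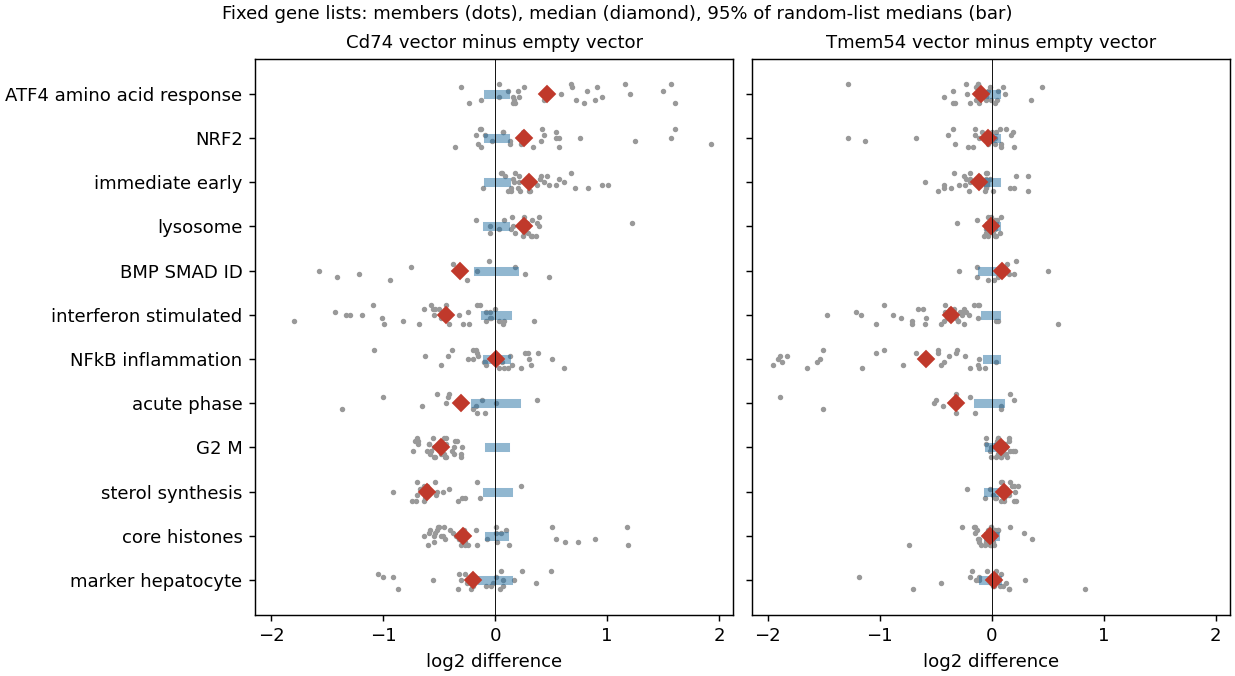
Log2 difference of the members (dots) and the median (diamond) of fixed gene lists for the Cd74 and the Tmem54 array against the empty-vector array, with the range of 95% of random-list medians as a bar. Interferon-stimulated genes have medians of -0.44 and -0.37, and the NF-kB list has medians of 0.004 and -0.59.

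With the Tmem54 vector, inflammatory genes regulated by NF-kB and interferon-stimulated genes were lower than with the empty vector, and fewer genes passed 2-fold. Of 15521 genes compared, 81 were at least 2-fold higher and 126 lower, of which 50 and 65 were bounds. Centring on the median of detected probes gave 72 higher and 167 lower, so that 30.1% of the genes counted were higher against 39.1%. Normexp correction left 32 higher and 34 lower, and a filter for bright genes left 5 and 12. The NF-kB list had a median of -0.59 over 29 members (percentile 0.00), with 28 members below 0, 11 at least 2-fold lower and 0 higher. The chemokine gene Ccl20 differed by -1.95, the granulocyte growth factor gene Csf3 by -1.91, the siderophore-binding lipocalin gene Lcn2 by -1.89, and the neutrophil chemokine genes Cxcl1 and Cxcl5 by -1.87 and -1.83. Ccl7 differed by -1.65. Next-brightest probes of 12 members gave a median of -0.40. Interferon-stimulated genes had a median of -0.37 over 37 members (percentile 0.00), with 4 at least 2-fold lower, among them Oas2 (-1.47), Irf7 (-1.21) and Gbp3 (-1.17). The acute phase list had a median of -0.32 over 14 members (percentile 0.01), and the serum amyloid gene Saa3 differed by -1.51. It shares 3 members with the NF-kB list, Saa1, Saa3 and Lcn2, and without them its median was -0.19 (percentile 3.06), which does not stand apart. Normexp correction gave -0.12 for the whole list. The acute phase list was not particular to Tmem54. On the Cd74 array it had a median of -0.305 against the empty vector (percentile 0.08). Without the shared members that median was -0.41 (percentile 0.1), which still stands apart. The ATF4 list had a median of -0.096 over 30 members (percentile 0.00), with Slc7a11 at -1.28. G2/M and sterol synthesis medians were 0.079 and 0.11 (percentile 100 for both). Fibroblast and stellate cell markers had a median of 0.11 (percentile 99.91) and cholangiocyte and progenitor markers 0.095 (percentile 98.92). Centring on the median of detected probes moved the median of all genes to -0.132 and these 4 list medians with it, to -0.050, -0.018, -0.016 and -0.034 in the same order, each above that of all genes. Macrophage and B cell markers had a median of -0.042 over 11 members (percentile 18.76).

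The highest bright genes on the Tmem54 array were Ephb2, a receptor tyrosine kinase (1.84), Mid1, a microtubule-associated ubiquitin ligase (1.61), and Slc41a1, a magnesium transporter (1.42). The next-brightest probes of Mid1 and Slc41a1 gave -0.04 and -0.30. Below 2-fold were Angpt1 (0.91), H2-Q1 (0.85), the albumin gene Alb (0.83), Fmo1 (0.73), Psca (0.68), Fgf1 (0.56) and Tuba8 (0.56). The 10 lowest bright genes were Lcn2, Cxcl1, Cxcl5, Ccl7, Saa3, Irf7, Tnip3 (-1.50), Rtp4 (-1.49), the CoA diphosphatase gene Nudt7 (-1.18) and Apol9b (-1.11). The largest bounds after Tmem54 were at least 27.43-fold higher for Lrrn1 and 22.22-fold for Gm31925, and at least 12.4-fold lower for Gpam, a glycerol-phosphate acyltransferase gene, 12.38-fold for Lipo1 and 10.25-fold for Pik3c2g.

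Set directly against the Tmem54 vector, the Cd74 vector was higher for NF-kB genes, among other lists, and lower for mitotic, sterol synthesis and several cell type marker genes. Of 15423 genes compared, 251 were at least 2-fold higher and 261 lower, against 94 and 103 with normexp correction and 57 and 71 with the filter for bright genes. The NF-kB list had a median of 0.61 (percentile 100) with 13 of 29 members at least 2-fold higher. Against the empty vector its median was 0.004 on the Cd74 array (percentile 42.59) and -0.59 on the Tmem54 array. Also at percentile 100 against Tmem54 were the immediate early (0.505), ATF4 (0.41), NRF2 (0.31), lysosome (0.25) and p53 target (0.25) lists. Next-brightest probes of 12 NF-kB members gave 0.32, with 2 at least 2-fold higher. Interferon-stimulated genes had a median of -0.013 over 35 members (percentile 20.47), while next-brightest probes of 13 members gave 0.19, with 10 above 0. Sterol synthesis genes had a median of -0.69 and G2/M genes -0.54 (percentile 0.00 for both). Lower too were the fibroblast and stellate cell markers, with a median of -0.26 (percentile 0.05), the cholangiocyte and progenitor markers, with -0.23 (percentile 0.72), and the hepatocyte markers, with -0.14 (percentile 0.69). The highest bright genes after Cd74 (9.0) were Cox6a2 (3.48), Slc7a11 (2.84), Gm10639 (2.78) and Angptl6 (2.34). The lowest bright genes were Angpt1 (-2.97), H2-Q1 (-2.62), Psca (-2.41), Zscan4f (-2.39) and AF067061 (-2.29).

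Genes at least 2-fold from both other arrays on the same side numbered 240 for Cd74 (130 higher, 110 lower), 107 for Tmem54 (65 higher, 42 lower) and 86 for the empty vector (77 higher, 9 lower). The 77 genes higher on the empty-vector array include Irf7, Oas2, Gbp3, Rtp4 and Apol9b. The same counts are the overlap of the calls, with 77 genes lower and 9 higher on both vector arrays than on the empty-vector array. Of these, 20 of the lower and 4 of the higher genes were measured in both comparisons, and the others were bounds. The 86 fell to 24 among genes well above background on both arrays compared, to 22 with normexp correction and to 3 among bright genes. Among the 15355 genes compared on both arrays, 219 were lower and 73 higher with Cd74 and 126 lower and 39 higher with Tmem54. Independent lists of these sizes would share 1.8 lower and 0.19 higher genes, which leaves out the shared control, so the overlap has no value expected without a change. Across these genes, which are not independent replicates, the Cd74 and Tmem54 differences had a Pearson r of 0.24 and a Spearman rank correlation of -0.012, against 0.50 and 0.48 in simulated unchanged arrays with an SD of 0.074 each. The covariance was 0.023 against 0.0054 simulated, a value set by the SD of 0.074. That SD came from measured Tmem54 differences and was given to all 3 arrays. The observed covariance includes bounds and the wider Cd74 differences, so the 2 covariances cannot be compared. The simulated correlations likewise assume equal noise on all arrays. With genes well above background on every array r was 0.027, and with bright genes it was -0.26, so the sign of r depends on the dim genes. The 1 control array cannot be split, and part of what the Cd74 and Tmem54 differences share may come from it.

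**Figure D3:**
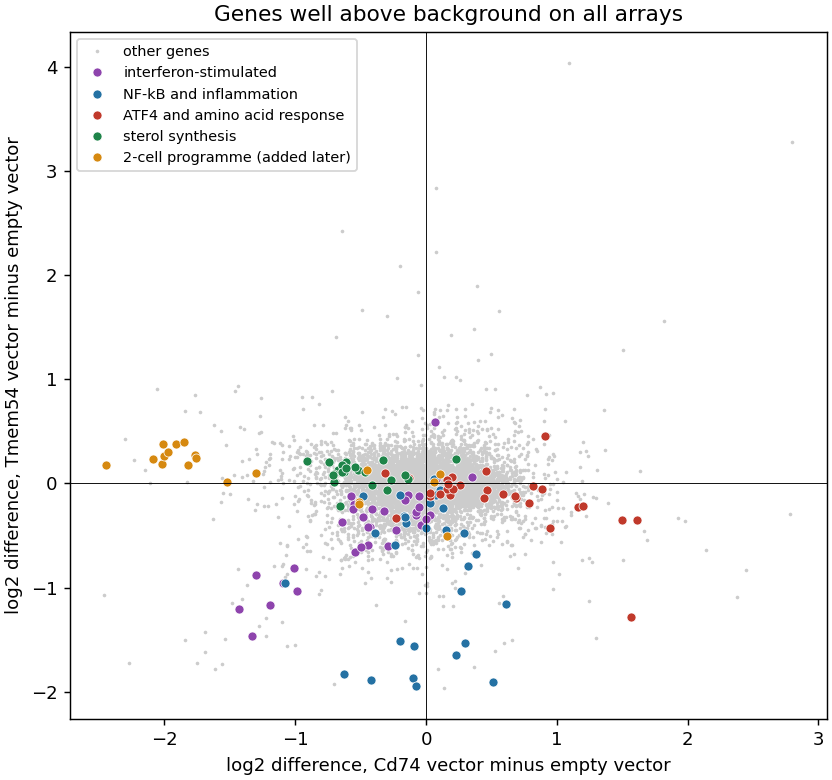
Log2 difference from the empty vector on the Cd74 array (horizontal axis) and on the Tmem54 array (vertical axis), 1 point per gene well above background on all arrays, without the transfected genes, with members of the named lists coloured. Interferon-stimulated genes such as Irf7 (-1.43 and -1.21) lie below 0 on both axes, and NF-kB genes such as Cxcl1 lie low on the vertical axis.

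Of the lists with enough members, 43 in each contrast, 19 stood apart for Cd74 against empty, 7 higher and 12 lower, and 7 stood higher and 12 lower for Tmem54 against empty. By chance 2.2 would be expected if the genes within a list varied independently, as in the random lists. Genes of a list may vary together, so more lists could stand apart without a vector effect, and 2.2 is no fair yardstick. Some lists also share members.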

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

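Probes with no gene symbol in the reference entered no comparison of the report. Of 5832 such probes compared, 72 were at least 2-fold higher on the Cd74 array than on the empty-vector control and 91 lower. On the Tmem54 array 56 were at least 2-fold higher and 58 lower. The highest bright probe on the Cd74 array lies on chromosome 11 from 120050006 to 120050065 (mm9), with a log2 difference of 4.72 from the empty vector and 4.60 from Tmem54. A probe on chromosome X from 11693554 to 11693613 differed by 1.71 on the Cd74 array and -0.79 on the Tmem54 array. These probes carry no replicate check.

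The tests on scaling, on the spread shared by probes of a gene and on a higher interferon state of the control culture were chosen after the result was seen. Differences from the empty vector spread wider on the Cd74 array, with a robust SD of 0.215 among genes measured on both arrays, than on the Tmem54 array, with 0.104. Noise of spots or probes is argued against, since the brightest and next-brightest probes of 6531 genes gave Cd74 differences correlated across genes at r = 0.53. Probe GC content with signal intensity, and position on the array, are argued against too, since the ratio of spreads was 2.11 and 2.15 after removing them. For hybridization noise the spike-ins alone do not decide, since 8 probes gave a ratio of 1.74, with an upper bootstrap limit of 2.91 that includes the 2.07 seen for genes. Noise that differs from probe to probe is argued against as the whole cause, since the robust SD shared by the brightest and next-brightest probes of 6448 genes was 0.156 for Cd74 and 0.059 for Tmem54, a ratio of 2.66 with a lower bootstrap limit of 2.46. Labelling or RNA quality, which act on whole transcripts, were not tested. The Cd74 vector and any other difference between cultures or samples stay open, as 1 array each cannot separate them.

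Interferon-stimulated genes were lower on both vector arrays than on the empty-vector array. Scaling is argued against, as the list medians stayed at -0.328 and -0.449 relative to genes of the same expression. Noise of single probes is argued against for the Tmem54 array, where next-brightest probes of 14 members gave a median of -0.342 with a spread of 0.049 and all 14 lay below 0. It stays open for the Cd74 array, where those of 15 members gave -0.164 with a spread of 0.156 and 11 lay below 0. The limit set beforehand applied to the higher of the 2 medians, that of the Cd74 array, which missed it. Reading each array on its own was not part of that limit. A higher interferon state of the empty-vector culture cannot be told apart from an effect of both vectors, since both arrays share the 1 control. The Cd74 and Tmem54 arrays differed by a median of -0.013. Next-brightest probes of 13 members gave 0.188 with a spread of 0.061, and 10 lay above 0. How far these 2 arrays differ for this list thus depends on the probe.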

How the results depend on the processing

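The settings that leave out members or take the next-brightest probe of each gene, and the correlation without the transfected genes, were chosen after seeing the data, and all other alternatives were fixed before. Of 172 differences of named genes that reached 2-fold, 172 kept their direction under the 6 scalings and probe rules, and 120 also stayed at 2-fold. Median centring, the authors' values and the 75th percentile over detected probes shift all differences alike, by far less than 2-fold. Direction under these scalings was thus fixed in advance and says nothing on stability. It could change only under normexp correction, quantile normalization and the mean over a gene's probes. A bound read by the same probe could not reverse under normexp correction or quantile normalization either. Its sign was set by which array was well above background. The next-brightest probe is not among the 6 settings. Of 42 such differences with a next-brightest probe, 37 kept their direction under it and 21 stayed at 2-fold. The 5 that turned were Guf1 for Cd74 against empty (-0.06), Mid1 (-0.04) and Slc41a1 (-0.30) for Tmem54 against empty, and Mid1 (0.12) and Vwf (-0.11) for Cd74 against Tmem54. Of the differences for Cd74 against empty, 937 were bounds, since signal over background limits what can be measured for dim genes. Centring on the median of detected probes moved the median of all genes to -0.108 for Cd74 against empty and -0.132 for Tmem54 against empty, so list medians under it were read relative to that shift. A list was taken as moved when its median changed by more than its robust SD over the square root of its size. Causes of the changes below were not tested.

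Counts are given in the order higher and lower for Cd74 against empty, Tmem54 against empty and Cd74 against Tmem54, then genes set apart for Cd74, Tmem54 and the empty vector. They were 160, 219, 81, 126, 251, 261, 240, 107 and 86 in the main setting. Normexp background correction gave 58, 61, 32, 34, 94, 103, 85, 38 and 22. The filter for genes well above background on both arrays compared gave 62, 130, 31, 61, 140, 170, 127, 49 and 24. The filter for bright genes (brighter array at or above the median of detected probes) gave 25, 33, 5, 12, 57, 71, 50, 14 and 3. No filter on dim probes gave 753, 860, 515, 836, 946, 756, 745, 554 and 519. Counting every probe on its own gave 308, 401, 197, 246, 440, 470, 418, 221 and 188. A threshold of 1.5-fold gave 529, 647, 205, 386, 782, 739, 785, 274 and 203. A threshold of 3-fold gave 75, 77, 47, 56, 99, 103, 99, 52 and 40.

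The correlation of 0.24 moved to 0.009 with normexp background correction, 0.28 with the mean over a gene's probes, 0.027 with genes well above background on every array, -0.26 with the filter for bright genes (brighter array at or above the median of detected probes).

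Next come list medians that moved with normexp background correction. Transfected genes came to 6.91, ATF4 amino acid response 0.35, interferon stimulated -0.27, acute phase -0.12, hepatocyte -0.030, macrophage B cell -0.034, sterol synthesis -0.55, Cd74 against empty. Heat shock came to -0.018, immediate early 0.26, NOTCH targets 0.19, cytosolic ribosome 0.009, Cd74 against empty. ATF4 amino acid response came to -0.068, Tribbles AKT 0.057, MHC class II 0.037, interferon stimulated -0.25, acute phase -0.12, AHR battery -0.052, CDK inhibitors tumour suppressors 0.009, Tmem54 against empty. p53 targets came to -0.064, bile acid FXR 0.021, lysosome 0.016, core histones 0.001, cytosolic ribosome 0.012, respiratory chain 0.041, Tmem54 against empty. ATF4 amino acid response came to 0.28, macrophage B cell -0.048, immediate early 0.38, cytosolic ribosome 0.011, proteasome 0.007, respiratory chain -0.12, Cd74 against Tmem54.

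With median centring over detected probes, 8 medians changed sign with the shift of all genes, and beside that shift none of these 8 changed by more than its spread. They were tRNA synthetases -0.015, Cd74 against empty, and BMP SMAD ID -0.039, cholangiocyte progenitor -0.034, fibroblast stellate -0.016, G2/M -0.050, sterol synthesis -0.018, WNT targets -0.063, respiratory chain -0.096, Tmem54 against empty. Other values that differed were transfected genes 8.61, Cd74 against empty, and cytosolic ribosome 0.030, Cd74 against Tmem54.

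Others moved with quantile normalization. Transfected genes came to 8.79, CD74 MIF receptor 0.089, sterol synthesis -0.57, proteasome 0.025, respiratory chain -0.053, Cd74 against empty. MHC class II came to 0.033, AHR battery -0.051, cytosolic ribosome 0.003, respiratory chain 0.027, Tmem54 against empty. CD74 MIF receptor came to 0.17, proteasome 0.064, respiratory chain -0.077, Cd74 against Tmem54.

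Medians also moved with the authors' series matrix values. Transfected genes came to 8.72, cytosolic ribosome 0.013, respiratory chain -0.082, Cd74 against empty. ER chaperones UPR came to 0.040, G1/S replication -0.011, G2/M 0.090, heat shock 0.048, lysosome 0.006, core histones -0.002, cytosolic ribosome 0.018, Tmem54 against empty. Proteasome came to -0.004, respiratory chain 0.045, Tmem54 against empty. Cytosolic ribosome came to -0.004, proteasome 0.002, respiratory chain -0.12, Cd74 against Tmem54.

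A group moved with the 75th percentile over probes well above background on all arrays. Transfected genes came to 8.72, cytosolic ribosome 0.014, respiratory chain -0.082, Cd74 against empty. Core histones came to -0.023, cytosolic ribosome -0.002, proteasome -0.025, respiratory chain 0.024, Tmem54 against empty.

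Some medians moved with the mean over a gene's probes. Tribbles AKT came to -0.024, CD74 MIF receptor -0.003, NF-kB inflammation -0.083, CAR PXR -0.22, macrophage B cell -0.071, G2/M -0.52, sterol synthesis -0.53, Cd74 against empty. TGFB EMT came to -0.088, cytosolic ribosome 0.021, Cd74 against empty. tRNA synthetases came to -0.039, ER chaperones UPR 0.045, G2/M 0.060, CDK inhibitors tumour suppressors -0.010, lipogenesis -0.016, bile acid FXR -0.057, YAP TEAD -0.015, Tmem54 against empty. bHLH partners ID came to 0.087, lysosome -0.033, cytosolic ribosome 0.003, proteasome -0.026, respiratory chain 0.029, Tmem54 against empty. tRNA synthetases came to 0.24, interferon stimulated 0.046, acute phase -0.15, CAR PXR -0.24, NRF2 0.47, G2/M -0.58, sterol synthesis -0.63, Cd74 against Tmem54. TGFB EMT came to -0.14, Cd74 against Tmem54.

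Fewer medians moved with the filter for genes well above background on both arrays compared. Hepatocyte came to -0.084, Cd74 against empty. CAR PXR came to 0.19, Cd74 against Tmem54.

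Several moved with the filter for bright genes (brighter array at or above the median of detected probes). BMP SMAD ID came to -1.08, interferon stimulated -0.33, hepatocyte -0.084, Cd74 against empty. Tribbles AKT came to 0.068, interferon stimulated -0.27, acute phase -0.23, AHR battery -0.039, hepatocyte 0.083, Tmem54 against empty. ATF4 amino acid response came to 0.58, BMP SMAD ID -1.20, oncofetal progenitor 0.073, Cd74 against Tmem54.

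Added later were medians that moved with study-chosen or shared members left out. NRF2 came to 0.18, acute phase -0.21, Cd74 against Tmem54. Acute phase came to -0.41, Cd74 against empty. Acute phase came to -0.19, Tmem54 against empty.

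Also added later were medians that moved with the next-brightest probe of each gene. ATF4 amino acid response came to 0.22, interferon stimulated -0.16, NF-kB inflammation -0.095, G2/M -0.53, sterol synthesis -0.40, Cd74 against empty. NF-kB inflammation came to -0.40, NRF2 -0.17, BMP SMAD ID -0.055 (over 3 members), Tmem54 against empty. ATF4 amino acid response came to 0.33, NRF2 0.56, interferon stimulated 0.19, NF-kB inflammation 0.32, sterol synthesis -0.56, Cd74 against Tmem54.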

Other observations

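The list and the tests of the following pattern were chosen after the Cd74 differences were seen. Genes of the programme of the 2-cell mouse embryo were lower together on the Cd74 array. Of 25 members compared, 19 measured and 6 bounds, 16 were at least 2-fold lower and 0 higher than with the empty vector, 3 of the 16 as bounds, with a median of -1.76 (percentile 0.00). Zscan4c differed by -2.45, Zscan4a by -2.09, Tcstv3 by -2.00, Gm4340 by -1.97 and Usp17lc by -1.52. Zfp352, Sp110 and Arg2 did not share this, at 0.06, 0.11 and 0.16. Leaving out the 7 members already noted among the lowest genes, the median over the other 18 was -0.86, with 9 at least 2-fold lower. On the Tmem54 array the list's median was 0.22.

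Cross-hybridization to a shared sequence is argued against as the whole cause, because the 9 lower members that had not been noted before have probes in 8 groups without close sequence identity, where 1 shared sequence would give 1 or 2. The median over the groups of all members not noted before was -0.69 and missed the limit of -1 also set for this test. That median measures how far members fell, not whether they share a sequence, so the argument rests on the number of groups alone. That number cannot exclude that probes at different positions read transcripts of the same family, such as the Zscan4 or Usp17l genes. Of the 9, Gm8300 also shares its group with Gm2022, which had been noted before. Families of near-identical copies may thus still blur which member a probe reads. For dim probes as the whole cause, the test does not decide. The 19 members well above background on all arrays had a median of -1.77, but 7 of them were noted first because they were low. The other 12 had a median of -0.90 with a spread of 0.40, which missed the limit of -1 set for this test too. They lay below random lists of the same expression, whose 95% range began at -0.17, and 6 of the 12 were at least 2-fold lower. Of these 6, Gm8300 shares a probe group with Gm2022, which had been noted before. Zscan4a, Zscan4b and Zscan4c are of the same family as Zscan4f, also noted before. Random lists of unrelated genes do not allow for such families, so the 12 are no independent check. A lower share of cells in this state with the Cd74 vector stays open, as does a difference between cultures, since 1 array each cannot separate them.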
